A study of Drosophila melanogaster with 6 samples.

How the data were processed

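RNA of 6 samples of Drosophila S2* cells was measured on Affymetrix Drosophila 2.0 arrays, which measure each transcript with a set of short probes and a single biotin label. Per the labels, cells were grown at 27 °C in Schneider's medium with 10% fetal bovine serum, left untreated or given 1 µM 20E for 24 h, and extracted with Trizol as total RNA. The group and the replicate number of each sample were taken from its title.

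The authors deposited 1 linear intensity per probe set and array, for 18769 probe sets. The step from probes to probe sets, the background correction and the scaling are not given in the sources used here. The deposited values run below 0, which a linear background subtraction can give, and 736 cells are empty. Between 373 and 968 values per array lie below 0 (1.99% to 5.29%). Medians of the arrays differ by up to 0.38 and 2% trimmed means by up to 0.44 on the log2 scale. By a rule set before the data were examined, arrays that differ by over 0.1 in both are taken as not yet normalized. The intensities were therefore quantile normalized between arrays, values below 0 were set to a floor of 0, and log2(intensity + 16) was taken. The floor was chosen after the values below 0 were seen. Quantile normalization gives all arrays 1 distribution, so a change of most transcripts in one direction would be removed. The offset compresses differences of dim probe sets, and an untreated or treated value at or below 0 has no fold. Quoted normalized intensities are means ± SD of the normalized values before the floor.

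Treated and untreated arrays were compared per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 3 arrays per group, fewer where cells were empty), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Where empty cells or a left-out array left a group with 1 value, that value was assumed to vary like the other group. A fit could not be made for 2 probe sets. SE is the moderated standard error of the log2 difference. The eBayes prior had 2.89 degrees of freedom, and the median log2 difference over all probe sets was −0.02. In total 25 gene lists, fixed before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01 over 1 probe set per gene, the brightest on average, for 11541 genes with a value on all arrays. The p-values were Benjamini-Hochberg adjusted over the lists. Counts of risen and fallen members are given over all probe sets tested and adjusted over the list alone. These counts include members with an empty cell, such as vri, E23, Dronc, Drs, if, Sesn and Cyp4e2, which the main list tests left out. Camera compares a list with all other genes, and the genes of a list may be correlated more strongly than the preset value, so the p with an estimated correlation is given for each called list.

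The genes named were chosen by a rule set before the data were examined. They are the 8 largest rises and 8 largest falls among called representative probe sets whose groups do not overlap and whose higher group mean is at or above the median of all probe sets, a preset group of hormone and immune genes whatever their values, and up to 4 called members of each list by adjusted p. Cth, Orc1, Eip63E and the genes of the families described among the other observations were named after their values were seen.

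Gene names came from a platform annotation table, updated by gene number through a RefSeq gene table of the assembly Release 6 plus ISO1 MT. Of the probe sets, 13647 had 1 gene symbol, 402 had several and 4720 were unnamed here, and 13544 of the single-gene probe sets were found in the gene table. No gene was named from a probe set with several. The 11982 genes named may therefore miss some that the arrays measure. Coordinates are not printed because the build of the array's annotation was not used here. Affymetrix control probe sets were not analysed here, so RNA integrity was not measured.

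The fit and the list test were tested on simulated data, with 18080 probe sets drawn with the spread of these arrays. The changed ones were drawn from those above the median level. Of 100 probe sets changed 2-fold, 8% were called, and of 100 changed 4-fold, 79%, with 5 of 92 calls at probe sets with no change. At this number of arrays most of the simulated 2-fold changes were thus missed. In all 200 probe sets were changed, against 957 called in the real data, and the share found depends on that number. A shifted list was called, and 0 of 24 other lists. Probe sets were drawn independently, so this could not show list calls made by genes that vary together.

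The alternatives tried were offsets of 1 and 64, no normalization between arrays, median centring, a filter at the 40th percentile of mean intensity, a trend and robust variance model, the replicate number as a block, leaving out probe sets whose suffix marks matches to several transcripts (_s_at, _x_at and _a_at), no variance moderation, leaving out each array in turn, and for lists an estimated correlation, fry and the mean of a gene's probe sets. Restrictions to probe sets above 0 and to probe sets with a value on all 6 arrays were added after the data were seen.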

Results

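S2* cells, a variant of the macrophage-like S2 line of Drosophila melanogaster, were compared with and without 20-hydroxyecdysone (20E), the steroid hormone that drives moulting and metamorphosis in insects. Total RNA of 3 untreated samples and of 3 samples given 20E at 1 µM for 24 h was hybridised to Affymetrix Drosophila 2.0 arrays, 1 array per sample. Each array gave a linear intensity for up to 18769 probe sets, with between 9 and 456 empty cells per array. The median deposited intensity lay between 43.2 and 56.4 and the highest between 9083 and 10358. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. For the untreated samples, the sample records used here hold no time and no mention of solvent. Effects of solvent or of time in culture could therefore not be told apart from those of 20E. The small number of arrays limits the precision of every value.

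Across probe sets, which are not independent replicates, the log2 values of array pairs correlated with r from 0.881 to 0.955 among untreated samples and from 0.867 to 0.952 among treated samples. Pairs of an untreated and a treated array had r from 0.797 to 0.884. The first principal component, with 46.1% of the variance, placed the untreated arrays at −64.5 to −21.6 and the treated arrays at 37.4 to 53.3. The second, with 29.3%, placed treated replicate 2 at 69.9 and untreated replicate 1 at −47.8, apart from the other arrays of their groups.

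**Figure D1:**
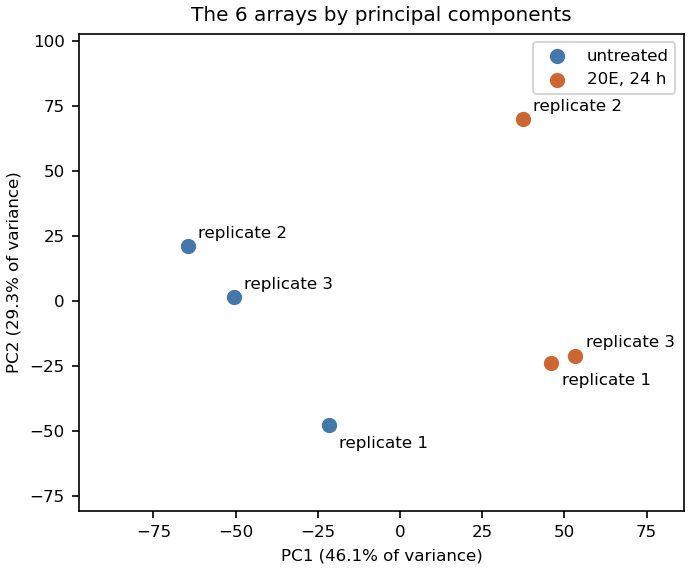
Scores of the 6 arrays on the first and second principal components (log2 units) of the normalized log2 values, with blue points for untreated and orange points for 20E-treated samples. The groups separate along the first component, which holds 46.1% of the variance, and treated replicate 2 lies highest on the second, at 69.9.

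The comparison of treated with untreated cells asked which transcripts changed in S2* cells after a day of hormone. In the treated cells, the small heat shock protein genes Hsp27 and Hsp26, the hormone-inducible regulators Eip78C, vri and Eip93F, the engulfment receptor genes NimC4 and drpr, the fascin gene sn and the integrin gene scb rose. The genes cDIP, aos and Nplp2 fell, and the list of cell cycle and DNA replication genes shifted downward by camera with a preset correlation, but was not called with an estimated correlation or by fry. The transcript of sn, which encodes an actin-bundling protein, rose from 1.36 ± 28.7 to 5010 ± 551 normalized intensity units (SD, n = 3 per group), and Nplp2 fell from 5170 ± 227 to 101 ± 5.83. Most of the measured antimicrobial peptide, neuron, muscle and salivary gland genes did not pass the test. Only 9 of the 17 antimicrobial peptide genes on the list were measured.

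Of 18767 probe sets tested with limma, 957 changed at an adjusted p under 0.05, with 567 higher and 390 lower in treated cells. Of these, 908 changed at least 2-fold, with 547 higher and 361 lower. At an unadjusted p under 0.05 there were 3230, with 1653 higher and 1577 lower. By 1 representative probe set per named gene, 447 genes rose and 338 fell, and 132 called probe sets had no gene named here. Of the calls, 877 had a value on all 6 arrays and 15, all higher, had only 1 value in 1 group, which was assumed to vary like the other group. The treated and untreated values at hand of all 957 did not overlap, while 4107 of the 18080 probe sets with a value on all 6 arrays had groups that did not overlap, against 10% by chance. Without normalization between arrays the split was 723 higher to 307 lower. The count fell to 567 with an offset of 1 in place of 16, to 397 without variance moderation, and to 439, 423, 403 and 326 without treated replicate 1, treated replicate 3, untreated replicate 2 and untreated replicate 3.

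The 8 largest rises by the naming rule were those of sn, CG5080, sick, CG8757, NLaz, NimC4, Gs1 and Dtg. On the log2(normalized intensity + 16) scale, differences and ranks of genes with values near, at or below 0 depend on the offset. For sn (adjusted p = 0.000278), 2 of 3 untreated values were at or below 0, and its difference ranged from 6.10 to 10.6 across the alternatives tried. CG5080 rose from 9.39 ± 11 to 3760 ± 147 intensity units (SD, n = 3 per group, adjusted p = 8.72e-05), with 1 of 3 untreated values below 0. Gs1, a glutamine synthetase gene, was higher by 6.19 ± 0.32 on the log2 scale (SE, adjusted p = 0.000172), and Dtg, known as a target of Dpp signalling, by 6.15 ± 0.30 (adjusted p = 0.000149). Dtg was at 6.49 ± 5.39 units in untreated cells, and its difference ranged from 4.52 to 8.2 across the alternatives. The homologue of a neuron navigator gene, sick, rose from −1.84 ± 9.7 to 1780 ± 840 units (adjusted p = 0.000168) on 1 probe set, with 1 of 3 untreated values below 0, while its 6 other probe sets did not pass the test and differed by −1.66 to −0.15. For CG8757, for the lipocalin gene NLaz and for NimC4 the 3 untreated values were at or below 0, so no fold is given. Their treated levels were 1450 ± 206, 1260 ± 147 and 1230 ± 82 (SD, n = 3), each with an adjusted p of 2.63e-05.

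The 8 largest falls by the naming rule were those of cDIP, aos, Nplp2, btn, CG34330, aru, Nazo and Mnr. The transcript of cDIP, which encodes a cell-surface binding partner of Dpr proteins, fell from 2150 ± 423 to −8.31 ± 12 intensity units (adjusted p = 2.63e-05), with 2 of 3 treated values below 0, and its log2 difference ranged from −10.3 to −5.07 across the alternatives. For aos, a secreted inhibitor of the EGF receptor, the difference was −5.73 ± 0.28 (adjusted p = 0.000387, n = 2 untreated and 3 treated). Nplp2, a neuropeptide-like precursor also used as a plasmatocyte marker, differed by −5.47 ± 0.18 and the homeobox gene btn by −5.42 ± 0.19. The differences of CG34330, aru, Nazo and Mnr ran from −5.26 to −3.64, with adjusted p from 0.000687 to 0.00425, and 1 of 3 treated values of Nazo was below 0. The other probe set of Mnr differed by −0.633 (adjusted p = 0.658). All 16 of these genes kept their calls when any 1 array was left out. For aos, with no value on untreated replicate 1, leaving out another untreated array left 1 untreated value.

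**Figure D2:**
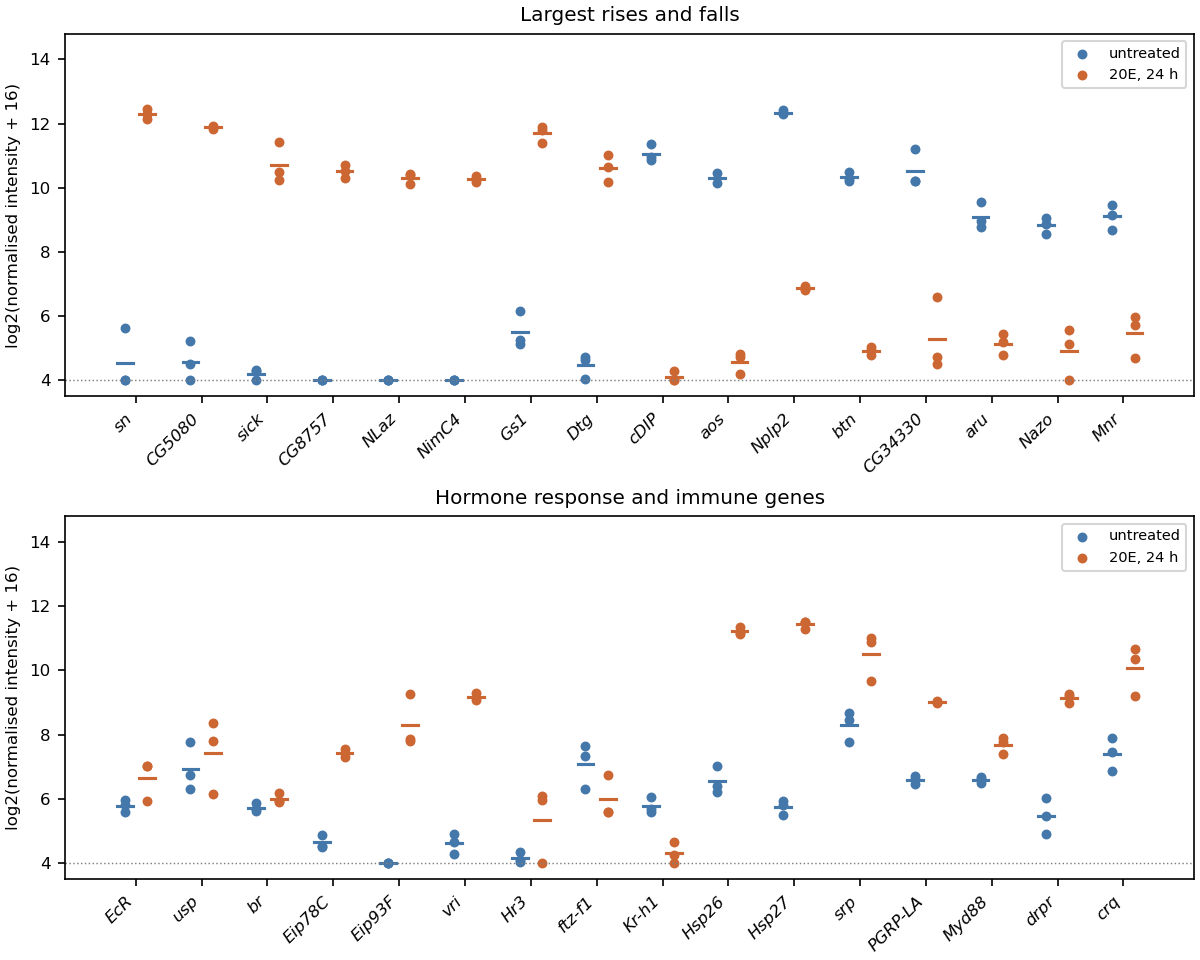
Log2(normalized intensity + 16) of 16 genes with the largest rises and falls (top) and of 16 hormone-response and immune genes (bottom), with a point per array and a bar at the group mean; the dotted line at 4 marks values at or below 0. Nplp2 has a mean of 12.34 in untreated and 6.87 in treated cells, and Hsp27 of 5.73 and 11.44.

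Among the transcription factors of the ecdysone cascade, 3 of 13 measured members rose, 1 fell and 9 did not pass the test, against 4 risen and 1 fallen adjusted over the list alone. Eip78C, a nuclear receptor, rose by 2.78 ± 0.20 on the log2 scale (adjusted p = 0.000669), from 9.12 ± 3.71 to 156 ± 15.1 intensity units. The leucine zipper gene vri rose by 4.56 ± 0.27 (adjusted p = 0.000771, n = 3 untreated and 2 treated). It was at 8.98 ± 5.32 intensity units in untreated cells, and its difference ranged from 3.1 to 5.98 across the alternatives. Eip93F, a regulator of metamorphosis, was at or below 0 in untreated cells and at 339 ± 221 in treated cells (adjusted p = 0.00187), while its other probe set differed by −0.15. Kr-h1, a response gene of juvenile hormone, fell from 39.4 ± 9.71 to 3.84 ± 4.66 intensity units (adjusted p = 0.0195), with 1 of 3 treated values below 0. The hormone receptor gene EcR differed by 0.87 ± 0.34 (adjusted p = 0.247), its partner usp by 0.50 ± 0.63 (0.77), Hr3 by 1.19 ± 0.55 (0.338, with 1 of 3 treated values below 0), ftz-f1 by −1.12 ± 0.46 (0.278) and the 20E-degrading enzyme gene Cyp18a1 by 0.28 ± 0.32 (0.746). Hr3 was at 1.93 ± 2.11 intensity units in untreated cells, and its difference ranged from 0.506 to 2.46 across the alternatives. Without treated replicate 2, EcR and Hr3 passed the test (adjusted p = 0.0268 and 0.00772). For br, the brightest probe set differed by 0.28 ± 0.19 (adjusted p = 0.539), while 2 others rose. Their log2 means went from 4.013 ± 0.0226 to 7.448 ± 0.595 (SD, adjusted p = 0.00174) and from 4.205 ± 0.190 to 6.555 ± 1.03 (adjusted p = 0.0437), with 2 and 1 of 3 untreated values at or below 0. Eip74EF and Eip75B were not analysed here. The list shifted upward (camera over 11 of the 13 members, vri not among them, adjusted p = 0.0228, and 0.62 with an estimated correlation). That call was lost with an offset of 1 (adjusted p = 0.146), without probe sets that can match several transcripts (0.315) and without treated replicate 1 (0.0657).

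Of 17 other genes known to respond to 20E, 6 rose, 1 fell and 10 did not pass the test, against 6 and 3 adjusted over the list alone. The small heat shock protein genes Hsp27 and Hsp26 rose by 5.70 ± 0.20 (adjusted p = 3.81e-05) and 4.68 ± 0.26 (adjusted p = 0.00022). E23, an ABC transporter gene, was at or below 0 in untreated cells and at 382 ± 342 in treated cells (n = 2, adjusted p = 0.0138). Dronc, an initiator caspase gene, rose by 1.64 ± 0.27 (adjusted p = 0.0269, n = 3 untreated and 2 treated), and ImpL2, which encodes an insulin-binding protein, by 1.60 ± 0.33 (adjusted p = 0.0426). The sixth, Eip63E (adjusted p = 0.0429), had only 1 treated value, so its call rests on the assumption that this value varies like the untreated ones. The 1 that fell, named after its value was seen, was Cth at −0.96 (adjusted p = 0.0398). No member of this list fell with an offset of 1, without normalization between arrays, with median centring, with the replicate block, without variance moderation, or on leaving out any 1 array except treated replicate 2. The rises numbered 3 with an offset of 1, 4 with the replicate block and 2 without variance moderation. They numbered 2 to 4 on leaving out any 1 array except treated replicate 2, and stayed at 6 with either change of normalization. This list was not called by camera (adjusted p = 0.709). That test covered 14 of the 17 genes, without the risen E23, Dronc and Eip63E, which lack a value on an array. Of 14 genes of ecdysteroid synthesis, uptake and turnover, 2 rose, both over all genes and adjusted over the list alone. These were E23 and Npc1a, a sterol transport gene that rose by 2.00 ± 0.42 (adjusted p = 0.0459; camera for the list, 0.709). Among 8 heat shock and stress genes, 2 rose (3 adjusted over the list alone), namely Hsp27 and Hsp26, and the list shifted upward (camera, adjusted p = 0.000864; adjusted p = 0.62 with an estimated correlation). Kr-h1 passed only without treated replicate 2 or 3 (highest adjusted p on leaving out 1 array, 0.0925), E23 was lost without any 1 untreated array (0.0845) and Npc1a passed only without treated replicate 2 (0.175). ImpL2 passed only without untreated replicate 1 or treated replicate 2 (0.187). Dronc, with no value on treated replicate 2, was lost without untreated replicate 2 or 3. Leaving out treated replicate 1 or 3 left Dronc with 1 treated value.

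In the IMD pathway, which carries the response to Gram-negative bacteria, 1 of 19 measured members rose, also adjusted over the list alone, and 18 did not pass the test. PGRP-LA, of the peptidoglycan recognition protein family, rose by 2.42 ± 0.18 (adjusted p = 0.000741), from 80.9 ± 8.07 to 501 ± 9.21 intensity units, and PGRP-LC was not analysed here. Of 16 Toll pathway members, 2 rose, or 4 adjusted over the list alone. The adaptor gene Myd88 rose by 1.08 ± 0.21 (adjusted p = 0.0322) and the Pellino gene Pli by 1.98 ± 0.42 (adjusted p = 0.0452). Both lists shifted upward (camera, adjusted p = 0.0235 for IMD and 0.0287 for Toll; adjusted p = 0.66 with an estimated correlation for each). Of 9 measured antimicrobial peptide genes (17 on the list), 1 rose, also adjusted over the list alone. It was the antifungal peptide gene Drs, from −4.4 ± 16.4 to 35.1 ± 3.84 intensity units (SD, n = 3 and 2, adjusted p = 0.0357), with 1 of 3 untreated values below 0. Of 7 other PGRP and lysozyme genes, 1 rose, also adjusted over the list alone, namely LysS, from −10.9 ± 13.8 to 127 ± 89.2 units (adjusted p = 0.0238), with 2 of 3 untreated values below 0. The log2 differences of Drs and LysS ranged from 0.558 to 3.5 and from 1.43 to 5.87 across the alternatives. Camera called neither of these lists (adjusted p = 0.946 each). Of 8 JAK-STAT genes, 1 rose, or 2 adjusted over the list alone, namely Stat92E at 1.48 ± 0.32 (adjusted p = 0.049; camera for the list, 0.685). With median centring no member of the Toll, antimicrobial peptide or JAK-STAT lists passed. Myd88, Pli and Stat92E passed only without treated replicate 2 (highest adjusted p 0.146, 0.183 and 0.179), LysS only without treated replicate 1 or 2 (0.103), and Drs was lost on leaving out any 1 array (0.188). The IMD and Toll shifts were lost without treated replicate 1 (adjusted p = 0.0812 each), untreated replicate 2 (0.0619 and 0.0755) or treated replicate 3 (0.125 and 0.132), and without probe sets that can match several transcripts (0.0969 and 0.136).

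Of 21 phagocytosis receptors and opsonins, 3 rose, or 4 adjusted over the list alone, and none fell. Besides NimC4, a receptor for apoptotic cells, these were drpr, which encodes the engulfment receptor Draper and rose by 3.68 ± 0.31 (adjusted p = 0.00126), and the scavenger receptor gene crq at 2.67 ± 0.44 (adjusted p = 0.0195). The list missed the threshold by camera (adjusted p = 0.0583) and passed it by fry (0.00277). Of 12 GATA and haemocyte transcription factors, 1 rose, also adjusted over the list alone. It was the GATA factor gene srp at 2.23 ± 0.42 (adjusted p = 0.0319), from 308 ± 99.2 to 1580 ± 676 intensity units (camera for the list, 0.119). Of 15 plasmatocyte and matrix markers, 3 rose and 1 fell, as also adjusted over the list alone. The collagen IV genes vkg and Col4a1 rose by 1.54 ± 0.23 (adjusted p = 0.0135) and 1.23 ± 0.24 (0.0356), the protease inhibitor gene Timp by 2.32 ± 0.47 (0.04), and Nplp2 fell (camera for the list, 0.689). Of 11 crystal cell and lamellocyte markers, 1 rose (1 rose and 1 fell adjusted over the list alone), the prophenoloxidase gene PPO3 at 1.80 ± 0.25 (adjusted p = 0.00978; camera for the list, 0.946). Of 13 integrin and actin genes, 3 rose (3 rose and 1 fell adjusted over the list alone), namely sn and the integrin alpha genes scb at 3.15 ± 0.33 (adjusted p = 0.00334) and if at 2.51 ± 0.46 (0.0388, n = 3 untreated and 2 treated; camera for the list, 0.32). Untreated levels of scb and if were near 0, at 9.43 ± 6.85 and 6.84 ± 5.31 intensity units. Their differences ranged from 1.89 to 4.49 and from 1.35 to 4.04 across the alternatives. The call of srp held only without treated replicate 2 (highest adjusted p 0.129), those of crq and vkg only without untreated replicate 1 or treated replicate 2 (0.0989 and 0.0742). The call of if, with no value on treated replicate 1, was lost without any 1 untreated array. Leaving out treated replicate 2 or 3 left if with 1 treated value. Col4a1 passed only without untreated replicate 1 (0.149), Timp only without untreated replicate 2 (0.171; its other probe set rose by 2.64, adjusted p = 0.00142 with all arrays), and PPO3 was lost without untreated replicate 3 (0.0615).

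Of 21 cell cycle and DNA replication genes, 5 fell and none rose, and 10 fell adjusted over the list alone. The count of fallen members was 2 without normalization between arrays, 0 with median centring, 0 with an offset of 1, and 0 on leaving out any 1 array except treated replicate 2, where it was 2. PCNA, the sliding clamp of DNA polymerase, fell by 1.06 ± 0.19 on the log2 scale (adjusted p = 0.0266), from 961 ± 131 to 450 ± 11.9 intensity units. The helicase subunit genes Mcm3, Mcm5 and Mcm2 fell, with differences of −1.10 ± 0.22, −1.49 ± 0.30 and −1.16 ± 0.23 (adjusted p = 0.0358, 0.0388 and 0.0388). The fifth, Orc1, named after its value was seen, was at −0.88 (0.0457). The list had a median difference of −0.66 and shifted downward (camera, adjusted p = 0.000864; adjusted p = 0.66 with an estimated correlation), also with median centring (0.00321) and without normalization (0.00132), while fry did not call it (0.124). Of 16 autophagy genes, 2 rose, also adjusted over the list alone. The ubiquitin-like protein gene Atg8a rose by 1.52 ± 0.27 (adjusted p = 0.027) and the conjugating enzyme gene Atg3 by 0.96 ± 0.20 (0.0423). The list had a median of 0.47, with 13 members above 0, and shifted upward (camera, adjusted p = 0.00757; adjusted p = 0.66 with an estimated correlation). Of 10 cell death genes, 2 rose and 1 fell, or 3 and 1 adjusted over the list alone. The caspase genes Dcp-1 and Dronc rose, Dcp-1 by 1.91 ± 0.20 (adjusted p = 0.0034), and Debcl, of the Bcl-2 family, fell by 1.13 ± 0.22 (0.0362; camera for the list, 0.774). PCNA and Atg8a passed only without treated replicate 2 (highest adjusted p 0.137 and 0.114), and Atg3, Debcl, Mcm3, Mcm5 and Mcm2 were lost on leaving out any 1 array (0.183, 0.12, 0.162, 0.152 and 0.164), while both list shifts held on leaving out any 1 array.

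Of 16 detoxification genes, 2 rose and 1 fell, or 4 and 1 adjusted over the list alone. The cytochrome P450 gene Cyp4e2 rose by 3.39 ± 0.26 (adjusted p = 0.00175, n = 3 untreated and 2 treated), the catalase gene Cat rose from 558 ± 174 to 3690 ± 297 intensity units (0.00207), and the glutathione transferase gene GstD1 fell from 3980 ± 466 to 1060 ± 124 (0.00338; camera for the list, 0.971). Of 9 insulin and TOR genes, 2 rose (2 rose and 1 fell adjusted over the list alone), namely ImpL2 and the sestrin gene Sesn at 2.78 ± 0.30 (adjusted p = 0.00636, n = 3 untreated and 2 treated; camera for the list, 0.774). Of 9 glycolysis genes, 1 rose, also adjusted over the list alone, namely Tpi at 1.65 ± 0.25 (adjusted p = 0.0141; camera for the list, 0.119). Camera called the glycolysis list without normalization between arrays (adjusted p = 0.0356) and without untreated replicate 1. The list of cytosolic ribosomal proteins was drawn up by symbol alone, so a member such as RpLP0-like need not be one. Of its 41 genes, 1 rose and 1 fell (1 and 2 adjusted over the list alone). These were the paralogue RpS19b at 1.59 ± 0.23 (adjusted p = 0.0116) and RpLP0-like at −2.29 ± 0.34 (0.0122; camera for the list, 0.709). Sesn, with no value on treated replicate 2, was lost without untreated replicate 3, and leaving out treated replicate 1 or 3 left it 1 treated value. Tpi passed only without untreated replicate 1 or treated replicate 2 (highest adjusted p 0.0868). RpS19b was lost without untreated replicate 2 or 3 (0.0743), and RpLP0-like without treated replicate 1 or untreated replicate 3 (0.0752).

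Markers of other cell types were measured as a background. Of 8 fat body markers, 1 rose, also adjusted over the list alone, namely Fbp2, from 27.7 ± 13.9 to 561 ± 160 intensity units (adjusted p = 0.00126; camera for the list, 0.315, and fry, 0.0434). None of 8 neuron markers (camera, adjusted p = 0.315), 9 muscle markers (0.971) or 12 salivary glue and pupal gut genes (0.635) passed the test, while 1 salivary or gut gene fell adjusted over the list alone. In total camera with a preset correlation called 6 of the 25 lists, 5 upward and 1 downward, and with an estimated correlation it called 0. With the arrays regrouped so that each group mixed treated and untreated, camera with the preset correlation called up to 5 lists. Fry, which tests whether the genes of a list move one way on balance, called 7, all upward. They were the ecdysone cascade (adjusted p = 0.0397), other 20E-responsive (0.0282), GATA and haemocyte (0.0264), phagocytosis (0.00277), integrin and actin (0.0434), fat body (0.0434) and heat shock (0.00354) lists. Median, mean and camera direction differed in sign for 6 lists that camera did not call. Medians and means were −0.33 and 0.24 for ecdysteroid genes, −0.02 and 0.09 for antimicrobial peptides, −0.10 and 0.16 for other PGRPs and lysozymes, −0.03 and 0.12 for crystal cell and lamellocyte markers and −0.09 and 0.03 for muscle markers, all downward by camera. For plasmatocyte and matrix markers they were 0.03 and −0.10, upward by camera.

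**Figure D3:**
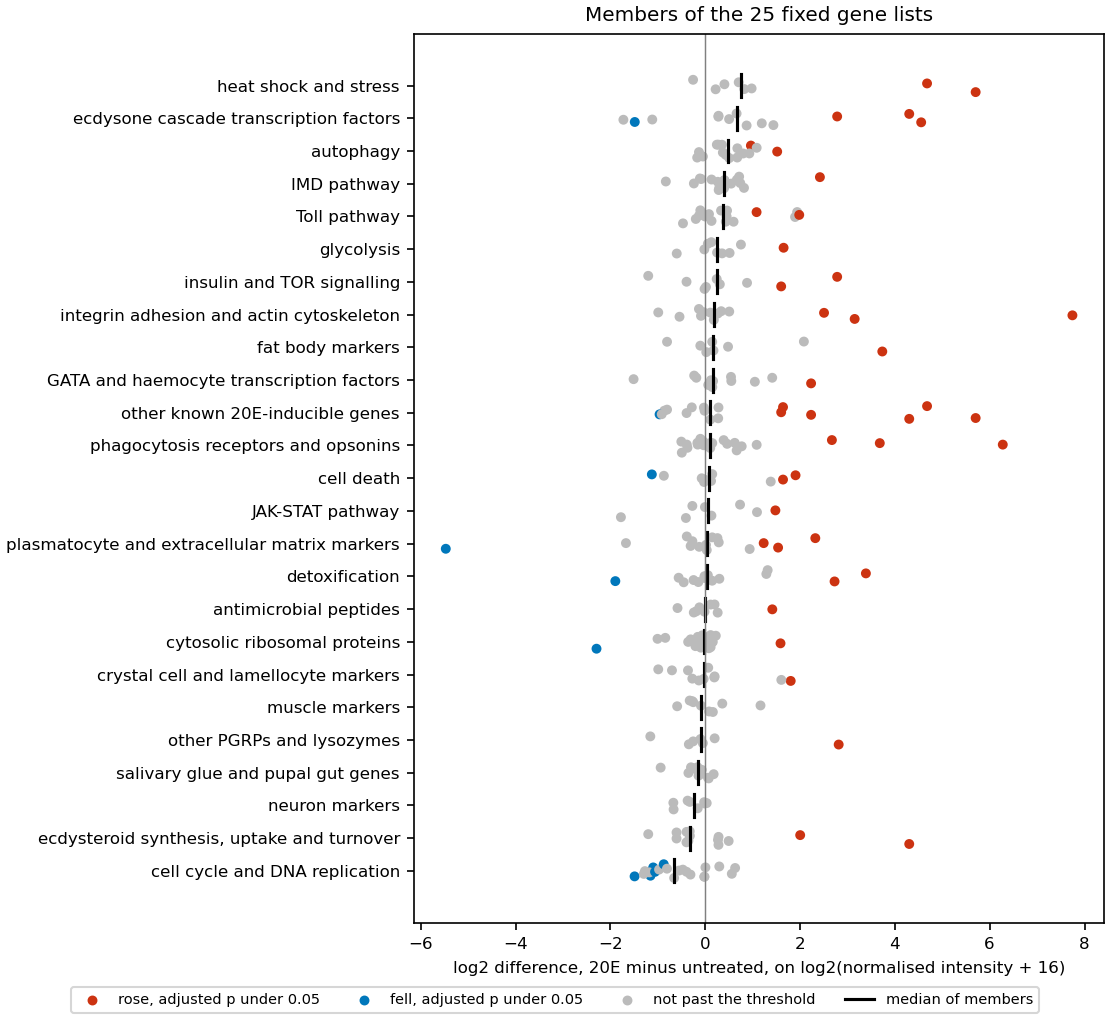
Differences (treated minus untreated, log2 of normalized intensity + 16) of the measured members of the 25 fixed gene lists, with a point per gene, a black bar at each list's median, and red or blue for genes that rose or fell at an adjusted p under 0.05. Positions of genes with no untreated value above 0 depend on the offset. The cell cycle list has the lowest median, −0.66, and the heat shock list the highest, 0.77.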

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

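The restrictions to probe sets above 0 or with a value on all 6 arrays were chosen after seeing the data. Over the alternatives, 1015 of 1015 values of the 63 named genes kept their direction, 200 lost the threshold and 2 newly passed it. The groups of every called probe set did not overlap, so the named calls could hardly reverse. Their kept direction therefore says little. Of 57 named calls, 29 held without each array in turn and 25 in every alternative that gave a value. Called probe sets fell from 957 to 567 with an offset of 1 (370 higher, 197 lower, all at least 2-fold), to 629 without suffixed probe sets, which removes the probe sets themselves (349 higher, 342 of these at least 2-fold), and to 397 without variance moderation (247 higher, 150 lower; at least 2-fold 339, 223 and 116). Elsewhere with all arrays they ranged from 818 to 1219. Leaving out 1 array gave 326 to 1069 calls (232 to 713 higher, 94 to 356 lower), of which 326 to 1027 were at least 2-fold (232 to 695 and 94 to 332). The lowest came without untreated replicate 3 and the highest without treated replicate 2. The cause was not tested. Camera called 6 lists with all arrays, 3 to 7 with 1 left out, 2 without suffixed probe sets and 0 with an estimated correlation, and the cause was not tested. Without suffixed probe sets the heat shock list had under 5 members and was not tested. The replicate number was a block only in an alternative, since no label says what it marks. Samples with the same replicate number deviated from their group means with correlations of 0.23, 0.37 and −0.02. Those with different numbers had correlations from −0.39 to 0.33. Not every sample correlated best with its own number (untreated replicate 1 with treated replicate 3, 0.33). So few values cannot decide whether the numbers mark pairs. With the replicate block there were 936 calls (572 higher, 364 lower), 770 of them shared, and 7 lists, the phagocytosis list being added. The comparison of 3 prime with 5 prime control probe sets was not run, since these were not analysed here. Values near or below 0 limit the measurement of dim probe sets: 36 calls had 1 group with no value above 0.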

Other observations

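The family test, the small nucleolar list, the exclusions of neighbouring pairs, the slopes with no shared untreated array, and the tests of normalization and of a batch of arrays numbered 2 were chosen after the results were seen. Among 76 families of genes with a shared name stem, each tested with Fisher's exact test (one-sided, Benjamini-Hochberg adjusted over families), the RNA polymerase subunits (Polr) had 8 of 21 measured members fallen (adjusted p = 4.15e-06). Of these, 6 were named as subunits of RNA polymerase I, which transcribes ribosomal RNA. Polr1E differed by −2.05 ± 0.26, Polr1A by −1.75 ± 0.22 and Polr1C by −1.75 ± 0.20 (SE, log2), with Polr1B, Polr1F, Polr1H, Polr2E and Polr3G from −1.76 to −0.93. The mitochondrial small ribosomal subunit genes (mRpS) had 5 of 25 fallen (adjusted p = 0.022), from −1.28 to −1.08. Those of the large subunit (mRpL) had 5 of 44 fallen and were not called (exact test, adjusted p = 0.194). The exact test treats genes as independent, while genes of a family may vary together over the same 6 arrays, so its p-values may be too small. It also compared each family with all 11980 named genes tested, whatever their level. Genes near the floor can hardly be called as fallen, so the p-values for falls may partly measure expression level. After several had been seen among the falls, a list of 8 core proteins of small nucleolar ribonucleoproteins, which modify ribosomal RNA, was drawn up. All 6 that were measured had fallen, with Fib at −2.59 ± 0.23, Nop60B at −2.55 ± 0.20, Nop56 at −2.40 ± 0.30, NHP2 at −2.29 ± 0.24, Gar1 at −1.85 ± 0.31 and Nop10 at −1.72 ± 0.23. No test is given, since the list was drawn up from the falls. Without normalization between arrays and with median centring all 6 still fell. On leaving out 1 array, 3 to 6 of the 6 passed, the fewest without untreated replicate 3, and all 6 stayed below 0. Of the 8 Polr genes, 6 were still called without normalization between arrays (adjusted p of the family by the exact test, 0.000345), 7 with median centring (1.18e-05) and 3 to 7 with 1 array left out. The family was no longer called without treated replicate 1 (0.0807), untreated replicate 2 (0.0848) or treated replicate 3 (0.112). The mRpS call was lost with either change of normalization and on leaving out any 1 array, with an adjusted exact p from 0.078 to 1.

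Of 9 measured genes of the Niemann-Pick type C families, which bind and move sterols, 4 rose (adjusted p = 0.0158 by the exact test), the only family of the 76 past the test for rises, and none fell. Npc2g was higher by 2.80 ± 0.20, Npc2a by 2.45 ± 0.21, Npc1a by 2.00 ± 0.42 and Npc2h by 1.25 ± 0.22. Npc2g and Npc2h are neighbours in the gene order, and the exact test treats genes as independent. The family was called without normalization between arrays (adjusted exact p = 0.0417, with the same 4 genes) and without treated replicate 2 (0.0352). It was lost with median centring (3 of the 4 genes called, 0.24) and on leaving out any other array (2 or 3 of the 4 called, 0.141 to 0.463).

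Among the 10 splits of the 6 arrays into groups of 3, the real one gave 957 changed probe sets and the highest other 0, 908 and 0 changed at least 2-fold, and 6 and 5 shifted lists. No other split gave a result as large, but 10 splits are too few for a share under 0.05. Every other split put treated and untreated arrays in both of its groups, so any treatment difference widened the spread within groups. Its 0 changed probe sets therefore cannot decide how far the 957 stand out. For lists the margin was small, with 5 and 4 calls in splits with 0 changed probe sets, against 6 in the real one. The number of list calls at the preset correlation thus hardly set the real split apart.

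Treated replicate 2 stood apart from the other treated arrays. A weaker response of that sample stays open. Over 981 probe sets called without it, its differences from untreated cells had a slope of 0.87 on those of the other treated arrays. The 95% bootstrap interval over probe sets was 0.848 to 0.892, above a bound of 0.8 set before the test. The like slope was 0.966 for treated replicate 1 and 0.994 for treated replicate 3 (400 and 393 probe sets). In each of these slopes both sides share the untreated mean. With no shared untreated array the slope of treated replicate 2 was 0.926 and 0.938 over untreated replicates 2 and 3 (410 and 180 probe sets) and 0.482 over untreated replicate 1 (1880 probe sets). For the other treated arrays it was 0.873 to 1.03, over 45 to 128 probe sets, so these slopes rest on different probe sets. Noise stays open too, since the SD of its deviations over probe sets with no call was 1.03 times the highest of the other arrays (0.732 against 0.71 for untreated replicate 1). Treated replicate 2 also had the most empty cells, 456 against 9 to 146 on the other arrays. It had the most values below 0 as well, 968 against 373 to 617. A batch shared by the arrays numbered 2 cannot be told apart from other differences between arrays, since their deviations correlated with r = 0.37 and those of the closest pair of different numbers with r = 0.33.

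More probe sets rose than fell, with 59.2% of calls higher. The share was 65.3% with an offset of 1, 54.1% with an offset of 64 and 55.5% without suffixed probe sets. At an unadjusted p under 0.05 by limma it was 51.2%, so the size of the excess depends on the offset and the threshold. If untreated values below 0 had made the excess, it would be gone among probe sets above 0 on all arrays. There 54.3% of calls were higher (exact binomial 95% interval 50.8% to 57.7%, which treats probe sets as independent). That share is lower than over all probe sets, so the floor may make part of the excess. Quantile normalization as the whole cause is argued against by 64.9% (61.6% to 68.1%) with median centring alone. With no normalization 70.2% of calls were higher. That share cannot decide, since the median log2 difference was then 0.06 and unscaled brightness alone could raise it. The processing before deposit stays open, as does an effect of the hormone itself, which was not tested apart from it.

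In the gene order of the reference table, 35 pairs of neighbouring measured genes had both risen, against a mean of 16.5 in 10000 shuffles (95% of shuffles 9 to 25, permutation p = 0.0002), which argues against chance placement. Fallen genes gave 14 pairs against 9.56 (permutation p = 0.1). Leaving out pairs with 1 name stem gave 32 against 15.9, overlapping genes 28 against 13.7, _s_at or _x_at probe sets 22 against 13.6 and _a_at probe sets 21 against 13.6 (permutation p = 0.0002, 0.0004, 0.02 and 0.03), so the count stayed above the shuffled mean in each, with the excess smaller without either kind of multi-transcript probe set and, without _a_at, at the upper limit of the central 95% of shuffles (7 to 21). With stems, overlaps and _s_at or _x_at probe sets out together it was 14 against 10.8, and with stems and all multi-transcript probe sets out, 11 against 10.6 (permutation p = 0.2 and 0.5), over 7739 and 7557 of 11883 pairs. An _a_at probe set can match several transcripts of 1 gene, so the last count does not test signal shared between genes. With _s_at or _x_at pairs alone left out an excess remained, and the count of 14 lay within the central 95% of shuffles (5 to 17) over fewer pairs. Signal shared between related genes and a coordinated response of neighbouring genes both stay open.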
